A study of Rattus norvegicus with 7 samples.

How the data were processed

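Total RNA from rat testis, extracted with Trizol and purified on RNeasy columns per the labels, had been hybridized to 7 Affymetrix Rat230_2 arrays: 3 untreated, 2 at 8 h and 2 at 20 h after cadmium chloride. The deposited values are a signal intensity per probe set on a linear scale, from MAS 5.0 per the series' design text, which also names GeneSpring 7.2. The trimmed mean, without the lowest and highest 2% of probe sets, was 250.1 on every array, which is the mark of scaling to one target. The experiment files of the instrument hold other information per the file headers, namely settings and no measured values, and were read for the array type, the hybridization day and the fluidics protocol. Untreated replicate 2, alone on day 2, was stained at 25 °C for 600 s under an older protocol, the other 6 arrays at 35 °C for 300 s. Its experiment file gives mouse as the sample type, where those of the other arrays give rat; its array type is Rat230_2 and its labels name a rat, and it was kept. The depth behind a value on an array is not a count, so no counting interval was given; the number of animals, which the labels call biological replicates, sets the precision, and the p-values of single probe sets are over animals. Those of the list test at a preset correlation compare the genes of a list with other genes.

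The table holds 31099 probe sets, 57 of them controls. Of the 31042 others, 20826 name 1 gene, 436 name several and 9780 have no gene name here; 20758 of the probe sets with 1 gene have their Entrez ID in the RefSeq table, and 0 symbols needed an update. No genome build is named for the probe sets, so no coordinates are given. Values were analysed as log2(signal + 15), 15 being the 20th percentile of all values. Probe sets above their array's 40th percentile on at least 2 arrays were kept: 20857 probe sets, 15827 of them with 1 gene, for 11552 genes. No further normalization was applied. The median log2 fold change of all probe sets was -0.08 at 8 h, -0.05 at 20 h and 0.02 between the times; quantile normalization gave 0.01, 0.00 and -0.01 and scaling to one 75th percentile 0.02, 0.00 and -0.03.

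The 3 groups were fitted together in limma 3.58.1 under R 4.3.3 with eBayes and an intensity trend (residual degrees of freedom 4, prior 5.48), and p-values were adjusted by Benjamini-Hochberg over the probe sets kept, with a threshold of 0.05. The comparisons were 8 h against untreated, 20 h against untreated, 20 h against 8 h, and an F test over the 3 groups. Gene lists were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, the one with the highest mean, adjusted over 69 tests (23 lists, 3 comparisons). Camera with an estimated correlation, which then works with the 4 residual degrees of freedom, and fry were run beside it. In each list the members were also adjusted over the list alone. The same fits were run with the hybridization day as a block, which leaves 2 residual degrees of freedom. Same-day list medians were compared with 10000 random lists matched on mean expression. Probe sets at least 2-fold apart on the same day were counted where either array had a signal of 200 or more.

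The comparisons, tests, lists, named genes and alternative settings were fixed before the data were examined; the fit on day 3 arrays alone was added afterwards. The rule named, per comparison with untreated, the 6 genes with the largest rise and the 6 with the largest fall among those that passed and lay outside the untreated range, 4 and 4 for 20 h against 8 h, and the 2 largest changes per list among members that passed; no gene passed, so none was named this way. It also named, whatever their values, Mt1a (found as Mt1), Mt2A, Hmox1, Hspa1b, Cldn11, Ocln, Tjp1, Cdh2, Ctnnb1, Tgfb3, A2m, Star, Cyp17a1, Insl3, Inha, Prm1 and Tnp1; Hspa1b has no probe set of its own here. The lists, with measured genes, were: metallothioneins and metal transport (10 of 13), heat shock proteins and chaperones (16 of 19), Nrf2 and antioxidant genes (18 of 23), unfolded protein and integrated stress response (18 of 19), immediate early genes (21 of 27), cytokines, chemokines and NF-kB targets (16 of 33), neutrophil and myeloid leukocyte (15 of 23), macrophage (14 of 17), red cell, platelet and plasma (7 of 18), endothelial (14 of 22), peritubular myoid and smooth muscle (14 of 14), Leydig cell and steroidogenesis (16 of 22), Sertoli cell (17 of 24), spermatogonial (9 of 16), spermatocyte (12 of 25) and spermatid (24 of 35) markers, tight junction (10 of 15), adherens, desmosome and gap junction and integrin (21 of 25), proteases, inhibitors and TGF-beta (18 of 23), hypoxia and glycolysis (21 of 23), p53 and apoptosis (14 of 20), cell cycle (19 of 20) and reference genes (11 of 15). Some genes stand in more than 1 list, such as Cldn5, Tjp1, Ctsl and Pgk1.

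The replicate numbers were not used to pair arrays: across 11552 genes, the differences between replicates 1 and 2 had correlations of -0.02, 0.08 and 0.17 between the groups. The fit was tested on simulated data with 200 changed probe sets and noise drawn around the spread that the fit estimated. That noise was independent between probe sets and held no day effect, unlike these arrays. At 8 h the fit recovered 5 of 200 at a log2 change of 1, 158 at 2 and 190 at 3, with 2, 6 and 11 false calls. At 20 h it recovered 12, 161 and 194, with 1, 11 and 12 false calls. Alternatives changed the pseudocount (1, or 40), the filter, the scaling, the trend, the arrays in the fit, the replicate or day block, the fold threshold, the probe set per gene and the list test, and left out each array in turn. Values were read and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.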

Results

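Gene expression was measured on rat whole-genome arrays in testes of adult Sprague-Dawley rats, an outbred stock. Rats were left untreated (n = 3) or received 1 intraperitoneal injection of cadmium chloride, a metal salt toxic to the testis, at 3 mg/kg and were killed 8 h (n = 2) or 20 h (n = 2) later. The labels call each array a biological replicate, read here as 1 animal, and the number of arrays limits the precision. The signal of each probe set had been scaled so that the trimmed mean was 250.1 on each array, and the median signal ran from 52.9 to 72.0. The arrays were hybridized on 3 days: untreated replicate 1 and 20 h replicate 1 on day 1, untreated replicate 2 alone on day 2, and untreated replicate 3, both 8 h arrays and 20 h replicate 2 on day 3. The first principal component carried 39.5% of the variance and separated the days, with scores from 19.3 to 31.1 for day 3 and from -39.7 to -32.9 for days 1 and 2. The log2 ratio of 3' to 5' signal of actin, a measure of RNA integrity and labelling, was 1.191 to 1.422 on day 3 and 0.733 to 0.985 on the other days. Because the days and the groups overlap in part, each comparison is given also with the day as a block and as same-day differences, that is, log2 signal of a cadmium array minus that of the untreated array of its day.

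The comparison of 8 h with untreated testis asked how the tissue had responded early after the dose. Endothelial markers were shifted down as a list: all 14 measured members had a lower mean at 8 h, with a median log2 fold change of -0.49 and a mean of -0.54 (limma's camera, adjusted p = 0.00059). With an estimated correlation between genes the adjusted p was 0.59, and fry, which tests the list alone, gave 0.35. Kdr, a receptor for vascular endothelial growth factor, had a signal of 55.7 ± 3.85 (SD, n = 3) in untreated testis and 16.1 ± 17.5 (SD, n = 2) at 8 h, a log2 fold change of -1.31 ± 0.43 (SE). Emcn, an endothelial sialomucin, had 61.7 ± 9.03 (SD, n = 3) in untreated testis and 26.4 ± 13.4 (SD, n = 2) at 8 h, a log2 fold change of -0.92 ± 0.42 (SE). Cldn5, the claudin of endothelial tight junctions, stood at 238.2 ± 5.43 (SD, n = 3) in untreated testis, at 62.7 on 8 h replicate 1 and at 236.1 on 8 h replicate 2. These 3 genes were chosen after their values were seen, and none passed over all probe sets. Kdr and Emcn were dim, in untreated testis within the range of the arrays' median signals, 52.9 to 72.0. At 8 h Kdr was near the 15 added before the log, so its fold change rests on values near the floor. The list's median same-day difference was -0.58 on 8 h replicate 1, at percentile 0.0 of random lists matched on mean expression, and -0.29 on 8 h replicate 2, at percentile 7.1. Over all arrays matched random lists had a median of -0.15 at 8 h. With the day as a block its median was -0.47 (adjusted p = 0.0022, and 0.91 with an estimated correlation). The call held when any 1 array was left out.

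Markers of later germ cells were shifted up at 8 h in the fit without the day. All 24 measured spermatid markers had a higher mean at 8 h, with a median log2 fold change of 0.32 and a mean of 0.29 (limma's camera, adjusted p = 4.7e-09; adjusted p = 0.70 with an estimated correlation). Prm1, a protamine that packs sperm DNA, had 21870 ± 5890 (SD, n = 3) in untreated testis and 28000 ± 1070 (SD, n = 2) at 8 h, a log2 fold change of 0.39 ± 0.24 (SE). Tnp1, a transition protein of spermatid chromatin, had a log2 fold change of 0.38 ± 0.22 (SE), and neither gene passed the test. Over all alternatives Prm1 ran from -0.06 to 0.59 at 8 h and Tnp1 from -0.02 to 0.58. Within day 3 the spermatid median was 0.02 on 8 h replicate 1 and -0.04 on 8 h replicate 2, and with the day as a block it was -0.01 (adjusted p = 0.99). The direction of the list test turned under quantile normalization (adjusted p = 0.86), and random lists matched on mean expression had a median of 0.22 over all arrays. The median of untreated replicate 3, the day 3 control, exceeded the mean of the other untreated arrays by 0.46. Spermatocyte markers were also shifted up, with a median of 0.11 and a mean of 0.17 over 12 members, 10 of them higher (limma's camera, adjusted p = 0.011; adjusted p = 0.70 with an estimated correlation). Random lists matched on mean expression had a median of 0.14, which put the spermatocyte list at percentile 32.0. Smc1b, a meiotic cohesin subunit, had 1558 ± 328 (SD, n = 3) in untreated testis and 2258 ± 247 (SD, n = 2) at 8 h, a log2 fold change of 0.55 ± 0.19 (SE), and was chosen after its values were seen; it did not pass over all probe sets. Same-day medians of the spermatocyte list were 0.09 and 0.13, and the median with the day as a block was 0.07 (adjusted p = 0.013, and 0.91 with an estimated correlation). The spermatocyte call was lost without untreated replicate 2 (adjusted p = 0.061), untreated replicate 3 (0.082) or 8 h replicate 2 (0.079), under quantile normalization (0.81) and with the replicate number as a block (0.10).

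Immediate early genes were not called at 8 h, with a median of -0.01 over 21 members (limma's camera, adjusted p = 0.75). Both 8 h arrays shared a day with an untreated array, and there they differed: the same-day median was 0.39 on 8 h replicate 1 and -0.02 on 8 h replicate 2. The list was called with the day as a block, with a median of 0.44 (adjusted p = 0.0092, and 0.91 with an estimated correlation). Untreated replicate 3, the only untreated array of that day, lay below the mean of the other untreated arrays by a list median of 0.27. Egr1, a zinc-finger transcription factor of this list, gave 208.1 on 8 h replicate 1, 58.2 on 8 h replicate 2 and 79.5 ± 23.2 (SD, n = 3) in untreated testis. Hspa1a, the inducible heat shock protein, gave 580.2 on 8 h replicate 1, 140.9 on 8 h replicate 2 and 178.9 ± 20.9 (SD, n = 3) in untreated testis. Slc7a11, the cystine transporter, gave 671.4 on 8 h replicate 1, 190.5 on 8 h replicate 2 and 252.6 ± 64.9 (SD, n = 3) in untreated testis. These 3 genes were chosen after their values were seen.

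Of 20857 probe sets tested with limma, 0 passed an adjusted p of 0.05 at 8 h, and the lowest adjusted p was 0.731. At an unadjusted p under 0.05 there were 1088 probe sets, 242 higher and 846 lower, where 1043 are expected by chance. All probe sets together had a median log2 fold change of -0.08, which was -0.02 with the day as a block and 0.01 under quantile normalization. The excess of lower probe sets therefore cannot be told apart from a shift of whole arrays. The day block gave 0 that passed and 1275 that had an unadjusted p under 0.05. Without 8 h replicate 2, 1 probe set passed, which has no gene name here, in a test that assumes the lone 8 h array to vary like the other groups; it had a signal of 3.6 on 8 h replicate 1 and 738.4 or more on the other 6 arrays. Of the 23 lists, 3 were called at 8 h, 0 of them with an estimated correlation and 0 with fry. Their members that passed numbered 0 over all probe sets and 0 when adjusted over the list alone.

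**Figure D1:**
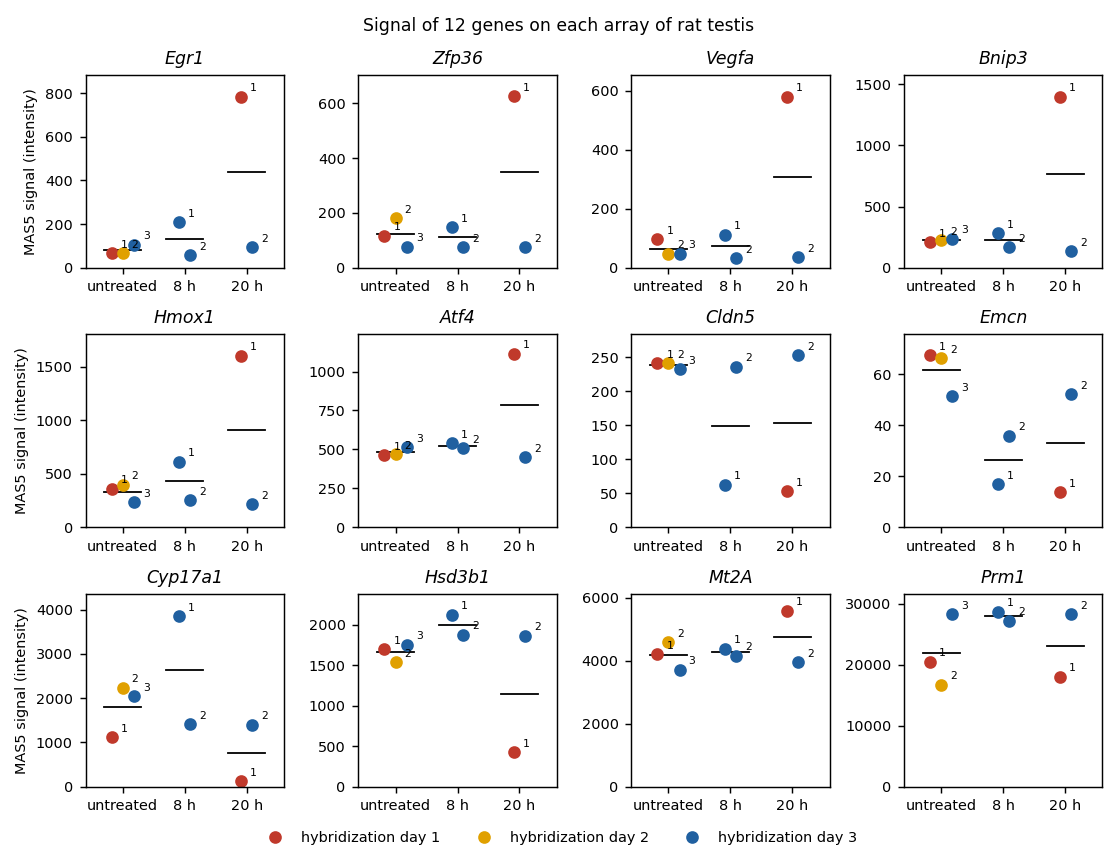
MAS5 signal (intensity, linear axes from 0) of 12 genes, some chosen after their values were seen, on the 7 arrays by group, with points coloured by hybridization day and numbered by replicate and a bar at the group mean. Egr1, Vegfa and Bnip3 stood highest on 20 h replicate 1, at 783.9, 578.8 and 1400.3, while 20 h replicate 2 gave 92.7, 35.5 and 133.4.

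The comparison of 20 h with untreated testis asked how the tissue had responded late after the dose. Endothelial markers were shifted down here too, against the same untreated arrays as at 8 h, so the calls at both times are not independent. All 14 members had a lower mean, with a median log2 fold change of -0.80 and a mean of -0.58 (limma's camera, adjusted p = 0.00014; adjusted p = 0.59 with an estimated correlation). Immediate early genes were shifted up, with 15 of 21 members higher, a median of 0.29 and a mean of 0.42 (limma's camera, adjusted p = 0.00014; adjusted p = 0.70 with an estimated correlation). Hypoxia and glycolysis genes were shifted up, with 14 of 21 members higher, a median of 0.14 and a mean of 0.28 (limma's camera, adjusted p = 0.0017; adjusted p = 0.70 with an estimated correlation). Genes of the unfolded protein and integrated stress responses were shifted up, with 12 of 18 members higher, a median of 0.13 and a mean of 0.22 (limma's camera, adjusted p = 0.0065; adjusted p = 0.70 with an estimated correlation).

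The 20 h arrays differed in these 4 lists. The same-day median of 20 h replicate 1 was -0.77 for endothelial markers, 0.54 for immediate early genes, 0.57 for hypoxia and glycolysis genes and 0.19 for the unfolded protein and integrated stress responses. On 20 h replicate 2 the same medians were -0.13, -0.04, -0.11 and -0.07. Matched random lists put the 4 medians of 20 h replicate 1 at percentiles 0.0, 100, 100 and 100, and those of 20 h replicate 2 at 36.8, 50.6, 1.7 and 10.4. With the day as a block the medians were -0.74 (adjusted p = 0.0032), 0.40 (0.0004), 0.09 (0.0022) and 0.10 (0.036), each with 0.91 under an estimated correlation. Without 20 h replicate 1 the adjusted p was 0.14 for endothelial markers, 0.81 for immediate early genes, 0.60 for hypoxia and glycolysis and 0.81 for the stress responses, and the direction of the immediate early and hypoxia lists turned. The hypoxia call was also lost without untreated replicate 1 (adjusted p = 0.053), and that of the stress responses without untreated replicate 2 (0.061) and with the filter at the 60th percentile (0.058).

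Among immediate early genes, Ier3, a stress-inducible regulator of survival, had 73.6 ± 16.1 (SD, n = 3) in untreated testis and 311.3 ± 218 (SD, n = 2) at 20 h, a log2 fold change of 1.72 ± 0.39 (SE). It passed when adjusted over the list alone, the 1 member of any called list to do so. Zfp36, which promotes decay of cytokine mRNAs, gave 625.6 on 20 h replicate 1 and 74.1 on 20 h replicate 2, with 124.7 ± 52.3 (SD, n = 3) in untreated testis. Among hypoxia genes, Bnip3, a mitophagy receptor induced by low oxygen, gave 1400.3 on 20 h replicate 1 and 133.4 on 20 h replicate 2, with 224.2 ± 13.5 (SD, n = 3) in untreated testis. Vegfa, the vascular growth factor, gave 578.8 and 35.5, with 63.4 ± 28 (SD, n = 3) in untreated testis. Adm, a vasodilator peptide, gave 322.3 and 18.4, with 31.2 ± 13.7 (SD, n = 3) in untreated testis. Atf4, the transcription factor of the integrated stress response, gave 1115.9 and 449.8, with 480.6 ± 27.9 (SD, n = 3) in untreated testis. The genes of this paragraph were chosen after their values were seen.

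The spermatid and spermatocyte lists were called at 20 h as well. Spermatid markers had a median of 0.11 and a mean of 0.12, with 23 of 24 members higher (limma's camera, adjusted p = 0.0017; adjusted p = 0.71 with an estimated correlation). Random lists matched on mean expression also had a median of 0.11, which put the spermatid list at percentile 44.3. Their same-day medians were 0.02 on 20 h replicate 1 and 0.04 on 20 h replicate 2, and the median with the day as a block was 0.04 (adjusted p = 0.28). The spermatid call was lost without untreated replicate 1 (adjusted p = 0.15) or untreated replicate 2 (0.25), and without 20 h replicate 2 (0.72), where its direction turned. Spermatocyte markers had a median of 0.10 and a mean of 0.10, with 8 of 12 members higher (limma's camera, adjusted p = 0.032; adjusted p = 0.70 with an estimated correlation). Matched random lists had a median of 0.08, and the list stood at percentile 76.0. Their same-day medians were 0.03 and 0.13, and the median with the day as a block was 0.08 (adjusted p = 0.13). The spermatocyte call was lost without untreated replicate 2 (adjusted p = 0.15), untreated replicate 3 (0.084), 20 h replicate 1 (0.17) or 20 h replicate 2 (0.17), with the replicate number as a block (0.12) and without the intensity trend (0.070). Quantile normalization ended the calls of both lists (adjusted p = 0.82 and 0.60) and brought those of the hypoxia and stress response lists to 0.054.

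Of the 20857 probe sets, 0 passed limma's adjusted p of 0.05 at 20 h, where the lowest was 0.531. At an unadjusted p under 0.05 there were 648 probe sets, 160 higher and 488 lower, below the 1043 expected by chance. Here too the median log2 fold change of all probe sets lay below 0, at -0.05, and at -0.04 with the day as a block. Under quantile normalization it was 0.00, so the excess of lower ones cannot be told apart from a shift of whole arrays. The day block gave 0 that passed and 1197 that had an unadjusted p under 0.05. Without 20 h replicate 2, the 20 h values are those of 1 array, assumed to vary like the other groups, and 8 probe sets passed, among them Hsd3b1 (log2 fold change -1.93, adjusted p = 0.031), Bnip3 (2.57, adjusted p = 0.039), Il33 (3.10, adjusted p = 0.039) and 2 probe sets of Fgl2. These genes were chosen after their values were seen. Of the 23 lists, 6 were called at 20 h, 0 of them with an estimated correlation and 0 with fry, and the count was 1 without 20 h replicate 1 and 3 without untreated replicate 2. Members of the called lists that passed over all probe sets numbered 0.

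**Figure D2:**
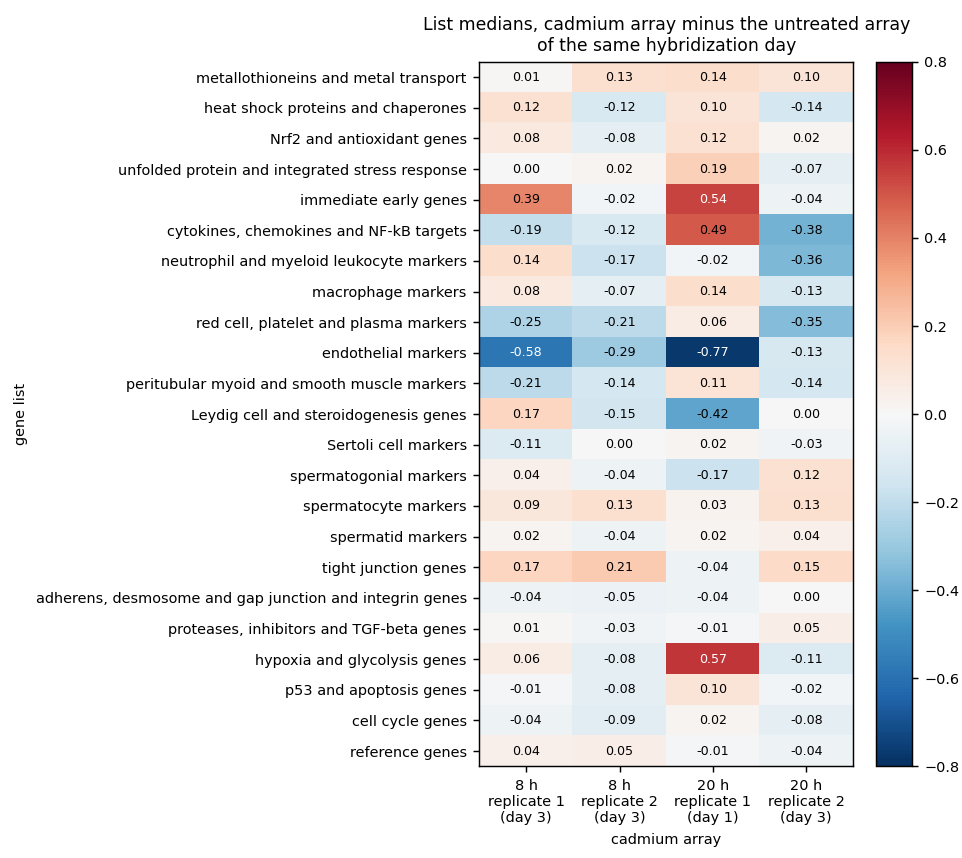
Median log2 signal difference of each of the 23 gene lists, for each of the 4 cadmium arrays minus the untreated array of the same hybridization day (colour scale in log2 units). The endothelial list stood at -0.58 on 8 h replicate 1 and -0.77 on 20 h replicate 1, and at -0.29 and -0.13 on the replicate 2 arrays of the same times.

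The comparison of 20 h with 8 h asked whether the response differed between the 2 times. Leydig cell and steroidogenesis genes were shifted down at 20 h, with 15 of 16 members lower, a median log2 difference of -0.34 and a mean of -0.55 (limma's camera, adjusted p = 3.2e-05; adjusted p = 0.70 with an estimated correlation). Cyp17a1, which makes androgen precursors from progestins, had 2634 ± 1720 (SD, n = 2) at 8 h and 765.4 ± 902 (SD, n = 2) at 20 h, a log2 difference of -2.39 ± 0.88 (SE). It gave 127.4 on 20 h replicate 1 and between 1116 and 3852.3 on the other 6 arrays. Cyp11a1, which starts steroid synthesis from cholesterol, gave 218.7 on 20 h replicate 1 and 964.9 on 20 h replicate 2, with 957.8 ± 125 (SD, n = 3) in untreated testis. Hsd3b1, the next enzyme of the pathway, gave 423.2 and 1862.7, with 1661 ± 114 (SD, n = 3) in untreated testis. Cyp11a1 and Hsd3b1 were chosen after their values were seen. The Leydig list's same-day median was 0.17 on 8 h replicate 1, -0.15 on 8 h replicate 2, -0.42 on 20 h replicate 1 and 0.00 on 20 h replicate 2. The same-day controls themselves differed in this list. Against the mean of the other untreated arrays, its median was -0.22 on untreated replicate 1 and 0.28 on untreated replicate 3. Against untreated testis the list was not called at 8 h (median 0.19, adjusted p = 0.089) or at 20 h (median -0.23, adjusted p = 0.078). With the day as a block its direction turned at 8 h (median -0.27, adjusted p = 0.66). At 20 h the list had -0.21 with that block (adjusted p = 0.025, and 0.91 with an estimated correlation). Its call between the times was lost with the day as a block (median -0.18, adjusted p = 0.067), without 8 h replicate 1 (0.15) and without 20 h replicate 1 (0.45).

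Immediate early genes were shifted up from 8 h to 20 h, with 20 of 21 members higher, a median of 0.37 and a mean of 0.42 (limma's camera, adjusted p = 0.00042; adjusted p = 0.70 with an estimated correlation). Hypoxia and glycolysis genes were shifted up, with 15 of 21 members higher, a median of 0.27 and a mean of 0.31 (limma's camera, adjusted p = 0.031; adjusted p = 0.70 with an estimated correlation). Cytokines, chemokines and NF-kB targets were shifted up, with 10 of 16 members higher, a median of 0.28 and a mean of 0.36 (limma's camera, adjusted p = 0.033; adjusted p = 0.70 with an estimated correlation). Icam1, a leukocyte adhesion molecule chosen after its values were seen, gave 318.5 on 20 h replicate 1 and 42.2 on 20 h replicate 2, with 46.9 ± 42.9 (SD, n = 2) at 8 h. Cytokine genes had same-day medians of -0.19 and -0.12 on the 8 h arrays, 0.49 on 20 h replicate 1 and -0.38 on 20 h replicate 2. Spermatid markers were shifted down, with 22 of 24 members lower, a median of -0.18 and a mean of -0.17 (limma's camera, adjusted p = 0.0013; adjusted p = 0.71 with an estimated correlation), where matched random lists had a median of -0.11.

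With the day as a block the medians between the times were 0.12 for immediate early genes (adjusted p = 0.62), 0.06 for hypoxia and glycolysis (0.40), 0.12 for cytokines (0.52) and 0.03 for spermatid markers (0.28), so that 0 lists were called. Without 20 h replicate 1 the directions of these 4 lists turned, with adjusted p of 0.45, 0.17, 0.81 and 0.81. The hypoxia call was also lost without untreated replicate 3 (adjusted p = 0.075) or 8 h replicate 2 (0.29), with the filter at the 60th percentile (0.058) and without the intensity trend (0.070). The cytokine call was also lost without untreated replicate 1 (adjusted p = 0.053), untreated replicate 2 (0.059), untreated replicate 3 (0.084), 8 h replicate 1 (0.099) or 8 h replicate 2 (0.076). It was lost too with the filter at the 60th percentile (0.26), only the 2 groups in the fit (0.083), the replicate number as a block (0.077) and quantile normalization (0.054). Quantile normalization turned the direction of the spermatid list (adjusted p = 0.66). Of the 23 lists, 5 were called, 0 with an estimated correlation and 0 with fry, and the count was 3 without untreated replicate 3, 3 without 8 h replicate 1 and 0 without 20 h replicate 1. Of the 20857 probe sets, 0 passed in limma, at a lowest adjusted p of 1. By chance 1043 are expected at an unadjusted p under 0.05, here and in the F test below. Between the times there were 401, 255 of them higher at 20 h and 146 lower. The day block gave 0 that passed and 656 at an unadjusted p under 0.05. Without 8 h replicate 2, 1 unnamed probe set passed, and without 20 h replicate 2, 1 did, that of Hsd3b1 (adjusted p = 0.025), each with 1 array left at that time. Members of the called lists that passed numbered 0 over all probe sets and 0 when adjusted over the list alone. Limma's F test over the 3 groups called 0 probe sets, with a lowest adjusted p of 0.525 and 630 at an unadjusted p under 0.05, and it called 1 without 8 h replicate 2.

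Metallothioneins bind cadmium and are induced by it in many tissues. Mt2A, the brighter of the pair fixed in advance, had 4172 ± 439 (SD, n = 3) in untreated testis, 4272 ± 158 (SD, n = 2) at 8 h and 4769 ± 1160 (SD, n = 2) at 20 h, log2 fold changes of 0.04 ± 0.17 (SE) and 0.18 ± 0.17 (SE). Mt1 had 91.4 ± 31.6 (SD, n = 3), 91.3 ± 24.3 (SD, n = 2) and 105 ± 33.7 (SD, n = 2). Hmox1, the heme oxygenase induced by heavy metals, had 329.7 ± 84.5 (SD, n = 3), 431.8 ± 257 (SD, n = 2) and 911.0 ± 981 (SD, n = 2), with 613.5 on 8 h replicate 1 and 1604.7 on 20 h replicate 1. The differences of Mt2A, Mt1 and Hmox1 did not pass the test. Over all alternatives the log2 fold changes at 8 h and 20 h ran from -0.15 to 0.28 and from -0.07 to 0.43 for Mt2A, from -0.25 to 0.59 and from -0.10 to 0.48 for Mt1, and from -0.35 to 1.27 and from -0.54 to 2.26 for Hmox1. The metallothionein and metal transport list had medians of -0.03 at 8 h (adjusted p = 0.79) and -0.06 at 20 h (0.75), where the test pointed up. Heat shock proteins and chaperones had 0.14 (adjusted p = 0.052) and 0.03 (0.39), and Nrf2 and antioxidant genes 0.08 (0.42) and 0.10 (0.15). The p53 and apoptosis list had -0.13 (adjusted p = 0.71) and 0.14 (0.42), and the cell cycle list -0.03 (0.89) and -0.01 (0.93), the test pointing up in both.

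The Sertoli cells and their junctions form the blood-testis barrier, a reported target of cadmium. Cldn11, the main claudin of that barrier, had 3024 ± 324 (SD, n = 3) in untreated testis, 3262 ± 547 (SD, n = 2) at 8 h and 3098 ± 641 (SD, n = 2) at 20 h. Log2 fold changes at 8 h and 20 h were 0.10 and 0.02 for Cldn11, each ± 0.18 (SE), and -0.23 and -0.08 for occludin (Ocln), each ± 0.26 (SE). They were -0.10 and 0.01 for Tjp1, each ± 0.14 (SE), and 0.02 and 0.02 for beta-catenin (Ctnnb1), each ± 0.15 (SE). N-cadherin (Cdh2) had -0.62 and -0.29, each ± 0.39 (SE), and -0.04 at 8 h with the day as a block. The growth factor Tgfb3 had -0.05 and -0.03, each ± 0.22 (SE), and the protease inhibitor A2m -0.03 and -0.05, each ± 0.15 (SE). Inha, the inhibin subunit of Sertoli cells, had 0.08 and -0.03, each ± 0.17 (SE). The differences of these 8 genes did not pass the test. Over all alternatives Cdh2 ran from -0.95 to 0.04 at 8 h and from -0.66 to 0.07 at 20 h, Ocln from -0.41 to 0.09 and from -0.31 to 0.14, Tjp1 from -0.53 to 0.01 and from -0.08 to 0.07, and the others from -0.20 to 0.36. Tight junction genes had medians of -0.11 at 8 h (adjusted p = 0.99, the test pointing up) and -0.03 at 20 h (0.95). The adherens, desmosome, gap junction and integrin list had -0.02 (adjusted p = 0.79) and 0.02 (0.57, with a mean of -0.01). Proteases, inhibitors and TGF-beta genes had 0.11 (adjusted p = 0.60, with a mean of -0.03) and 0.04 (0.082).

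Among the other cell types, Sertoli cell markers had medians of -0.04 at 8 h (adjusted p = 0.92) and 0.01 at 20 h (0.93, with a mean of -0.05), and spermatogonial markers 0.00 (0.65) and -0.15 (0.40). Macrophage markers had 0.16 (adjusted p = 0.13) and 0.08 (0.44), and neutrophil and myeloid leukocyte markers 0.09 (0.95) and -0.16 (0.31). Red cell, platelet and plasma markers had -0.23 (adjusted p = 0.34) and -0.12 (0.92). Peritubular myoid and smooth muscle markers had -0.08 (adjusted p = 0.65) and -0.02 (0.49, with a mean of 0.07). Reference genes had 0.03 (adjusted p = 0.46) and -0.03 (0.92, the test pointing up). The cytokine list had medians of -0.10 at 8 h (adjusted p = 0.30) and 0.07 at 20 h (0.49). Its tests left out members that the filter dropped, among them Cxcl1, Ccl2, Ptgs2 and Il6, which were highest on 20 h replicate 1. The hypoxia list had -0.04 at 8 h (adjusted p = 0.65, the test pointing up) and the stress response list 0.08 at 8 h (0.18). The 15 lists called in no comparison had same-day medians from -0.36 to 0.21, adjusted p between the times from 0.13 to 0.96, and adjusted p with the day as a block from 0.28 to 1. In the 14 calls the median, the mean and the test had one sign. Of the fixed Leydig cell genes, Star, which brings cholesterol into mitochondria, had log2 fold changes of 0.08 and -0.55 at 8 h and 20 h, each ± 0.38 (SE), Insl3, a peptide hormone, 0.50 and 0.16, each ± 0.26 (SE), and Cyp17a1 0.44 and -1.95, each ± 0.80 (SE), and these differences did not pass the test. With the day as a block they were -0.47 and -0.64 for Star, 0.04 and 0.00 for Insl3 and -0.42 and -1.76 for Cyp17a1. Over all alternatives, left-out arrays among them, Star ran from -0.50 to 0.60 at 8 h and from -0.99 to -0.11 at 20 h, Insl3 from 0.04 to 0.69 and from -0.25 to 0.57, and Cyp17a1 from -0.42 to 1.15 and from -3.61 to -0.29.

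Over 8461 bright probe sets, the SD of the log2 differences was 0.282 between the 8 h arrays, which shared a day, and 0.419 between the 20 h arrays, which did not. Among the untreated arrays, each of another day, it was 0.274 between replicates 1 and 2, 0.448 between replicates 2 and 3 and 0.46 between replicates 1 and 3. The closest pair was 8 h replicate 2 and 20 h replicate 2, with an SD of 0.167, a correlation across genes of 0.9934, where genes are not independent replicates, and 6 probe sets over 2-fold apart. Against the untreated array of its day, 20 h replicate 1 had 180 of 9384 probe sets at least 2-fold apart. On day 3, 8 h replicate 1 had 80 of 8652, 8 h replicate 2 had 76 of 8630 and 20 h replicate 2 had 68 of 8590. Over the 8461 bright probe sets these counts were 88, 60, 54 and 49, in the same order. The SDs were 0.293, 0.308, 0.286 and 0.278, so by SD 20 h replicate 1 did not stand apart.

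**Figure D3:**
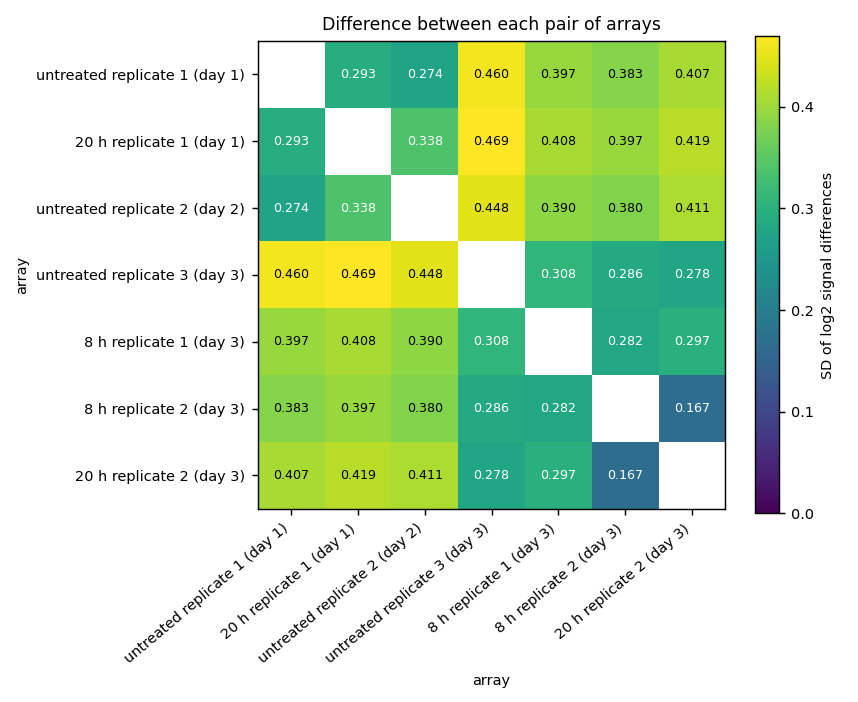
SD of the log2 signal differences (colour and printed value, log2 units) between each pair of the 7 arrays over 8461 bright probe sets, ordered by hybridization day. The pair of 8 h replicate 2 and 20 h replicate 2 stood at 0.167, and the other pairs from 0.274 to 0.469.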

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

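The tests of the hybridization day, RNA degradation, the animal of 20 h replicate 2, the shared day of the closest pair, one animal on both arrays and the other splits of the arrays were chosen only after the result was seen, while the test of brightness was not. The test of the difference between 20 h and 8 h called 5 lists, which marks them for a closer look: the median log2 difference was 0.37 for immediate early genes, 0.28 for cytokines, 0.27 for hypoxia and glycolysis, -0.34 for Leydig cell genes and -0.18 for spermatid markers. None of these 5 calls held with the day as a block, with an estimated correlation or with fry.

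The 20 h arrays differed from each other in the immediate early, hypoxia and Leydig lists. A shift common to both day 1 arrays is argued against. In immediate early genes 20 h replicate 1 exceeded the untreated array of its own day by a median of 0.54, at percentile 100 of matched random lists. Its same-day medians in the hypoxia and Leydig lists were 0.57 and -0.42. These values are part of the pattern itself and rest on 1 untreated array. Their percentiles are over genes and not over animals, so other effects of the day stay open. RNA degradation in 20 h replicate 1 is argued against by its log2 3' to 5' ratio of actin, 0.917, within the range of the other arrays, as were those of Gapdh and hexokinase. Whether cadmium failed to reach the animal of 20 h replicate 2 cannot be told apart from a weak response: it had 68 probe sets at least 2-fold from the untreated array of its day, below both 8 h arrays (80 and 76), but only 1 untreated array lay on that day, so the count between untreated animals of one day is unknown. The same question stands for 8 h replicate 2 and was not tested. Its same-day median was -0.02 in immediate early genes, against 0.39 on 8 h replicate 1. In endothelial markers these medians were -0.29 and -0.58. A difference in response between animals stays open and untested.

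The closest arrays were 8 h replicate 2 and 20 h replicate 2, of different groups. This pair was picked as the closest of all, so the other pairs of its day had to have higher SDs, and only the size of the gap bears on the day. Those SDs ran from 0.278 to 0.308 against 0.167 for this pair. By that gap, sharing the day was not enough to bring arrays this close. RNA of one animal or of close relatives on both arrays stays open: of 33 probe sets that fell into 2 distinct levels on the other 5 arrays, 100% put this pair on one side, and the highest share of another pair was 88.2%. On the less common side this pair shared 5, and other pairs shared 0 to 6. This pair had 6 of 8461 bright probe sets over 2-fold apart. Any pair this close would mostly fall on one side whatever made it close, so the share cannot tell relatedness from another cause. Some of the shared probe sets had been seen before that test, so one animal or relatives stays a hypothesis, and the design names no biological explanation.

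Spermatid markers were higher at 8 h than in untreated testis. The hybridization day is a candidate explanation: with the day as a block the list median was -0.01, against 0.32 without it. Brightness under global scaling stays open: the list median lay at percentile 100 of random lists matched on mean expression, but 21 of 24 members fell in the brightest of 20 bins, with a median log2 signal of 13.57 there against 12.33 for all its genes, so the matching was too coarse, and quantile normalization reversed the list (adjusted p = 0.86). At 20 h the list median of 0.11 equalled that of the matched lists. A change of germ cell content at 8 h stays open. The same-day medians, 0.02 and -0.04, and much of the value with the day as a block rest on untreated replicate 3. Its own median exceeded the mean of the other untreated arrays by 0.46. The highest signal of an array went by day, on untreated and cadmium arrays alike. It ran from 27237.7 to 28755.9 on the day 3 arrays and from 16767.1 to 20530.8 on the others. That goes with the day rather than with an unusual control alone. For the list itself no test told them apart.

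For the F test over the 3 groups, the count of other splits says nothing about chance: the real split called 0 probe sets, so that each of the 100 splits drawn from 105 had to call at least as many. Of these, 38 called any. The highest of the others called 2258, with untreated replicates 1 and 2 and 20 h replicate 1 as the group of 3, which keeps the day 3 arrays apart from the rest and points to a structure of the samples by day; its pairs put 8 h replicate 2 with 20 h replicate 2. With the day as a block, the F test also called 0.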

How the results depend on the processing

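The fit on day 3 arrays alone was chosen only after the result was seen; the other settings were chosen before. Over the alternatives, 111 of 137 values of the counts stayed within 1.5 times the reported count and 26 moved. The reported counts of probe sets were 0, so those that stayed at 0 say little about stability. None of the 909 values of the fixed genes was called under any alternative run. Of 294 list values, 201 kept direction and call, 77 lost the call and 16 reversed.

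Counts of probe sets were 0 throughout except as follows. Leaving out 1 array gave 0 to 1 at 8 h, 0 to 8 at 20 h, 0 to 1 between the times and 0 to 1 in the F test. Day 3 arrays alone gave 8, 2 and 2 for 8 h, 20 h and the F test, with 1 residual degree of freedom and lone untreated and 20 h arrays assumed to vary like the 8 h arrays. With the replicate block, 0 probe sets were called in each comparison, and 3, 5 and 4 lists, without the spermatocyte list at either time (adjusted p 0.10 and 0.12) and cytokines between the times (0.077).

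Lists called at 8 h, 20 h and between the times numbered 3, 6 and 5 as reported. They were 1, 2 and 3 under quantile normalization, 0, 0 and 0 with an estimated correlation, and 0, 0 and 0 with fry. Between the times they were 3 with the filter at the 60th percentile, 0 with the day as a block and 0 on day 3 alone, where 20 h gave 1. Leaving out 1 array gave 2 to 4, 1 to 8 and 0 to 7; without 1 of the arrays of a time, the lone array left is assumed to vary like the other groups.

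Some list directions reversed. Under quantile normalization spermatid markers had an adjusted p of 0.86 at 8 h and 0.66 between the times, and with the day as a block 0.28 between the times. Leaving out 1 array, the adjusted p ran from 1.1e-14 to 0.81 for immediate early genes, from 1.7e-11 to 0.60 for hypoxia and from 1.8e-08 to 0.72 for spermatid markers at 20 h, and between the times from 1.6e-10 to 0.45 for immediate early genes, from 6.1e-05 to 0.81 for cytokines, from 1.5e-06 to 0.81 for spermatid markers and from 4e-07 to 0.29 for hypoxia. The array whose loss reversed them was 20 h replicate 1 (hypoxia between the times 0.17), and for spermatid markers at 20 h it was 20 h replicate 2. On day 3 alone the reversed lists were at 0.98 for the stress responses at 20 h, 0.34 for hypoxia at 20 h and 0.30 between the times, and between the times 0.56 for immediate early genes, 0.79 for cytokines and 0.34 for spermatid markers. Calls lost there without a reversal were endothelial (0.30), immediate early (0.79) and spermatid (0.48) at 20 h, spermatid at 8 h (0.94) and Leydig between the times (0.34). The cause was not tested, save that camera with an estimated correlation works with fewer degrees of freedom and day 3 alone with fewer arrays. The estimated correlation was 0.66 for spermatid, 0.36 for Leydig, 0.34 for immediate early, 0.26 for hypoxia and 0.17 for cytokine genes, against the preset 0.01. By that estimate the p-values of these lists at the preset are too small. The stress response, spermatocyte and endothelial lists had 0.057, 0.045 and 0.015. Of the 14 calls, only that of endothelial markers at 8 h held with each array left out and on each scaling, and it too was lost with an estimated correlation (adjusted p = 0.59) and with fry (0.35). Simulated log2 changes of 1 were recovered in 2.5% at 8 h and 6% at 20 h. Under that noise, which held no day effect, changes of that size were mostly missed.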

Other observations

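The genes in this part were chosen only after their values were seen. Several inflammatory genes had their highest signal on 20 h replicate 1. Of the 16 cytokine list members tested, 11 were higher on that array than on the untreated array of its day and 5 lower. Cxcl1, Ccl2, Ptgs2 and Il6 were too dim on the other arrays to be tested. They belong to the cytokine list, and its results leave them out. Cxcl1, a neutrophil chemokine, gave 544.5 on 20 h replicate 1 and 17.3 or less on the other 6 arrays. Ccl2, a monocyte chemokine, gave 366.7 there and 34.8 or less elsewhere, and Ptgs2, the inducible cyclooxygenase, 296.0 there and 22.5 or less elsewhere. Il6 gave 118.2 there and 21.6 or less elsewhere. Serpina3n, an acute-phase protease inhibitor, gave 398.1 there and 39.7 or less elsewhere, a log2 fold change of 1.76 ± 0.80 (SE) at 20 h that did not pass the test. Il33, an alarmin that passed the filter, gave 307.3 there and 60.4 or less elsewhere. These are values of 1 array.

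Untreated replicate 3 had the highest signal of 3 fibrillar collagen genes. Col1a1 gave 736.6 there and 205.4 to 314.1 on the other 6 arrays, Col1a2 gave 1029 there and 164.1 to 466.5 elsewhere, and Col3a1 gave 760.4 there and 240.2 to 391.6 elsewhere.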
